A study of Homo sapiens with 16 samples.

How the data were processed

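The series holds 16 libraries of 2 kinds from 2 established human cancer cell lines. The first kind is a pooled CRISPR-Cas9 screen in RKO, a colon carcinoma line, carrying a reporter in which EGFP fluorescence reads out PD-L1 (the protein of CD274). The second kind is RNA sequencing of U2OS, an osteosarcoma line, with or without a knockout of MLLT6. The labels call the cells without the knockout mock cells, and they are called wild type here. Per the labels' protocols, treated cells received interferon gamma (IFNG) at 1.5 ng/ml with bovine serum albumin at 20 mg/ml, in the RNA experiment for 24 h. No albumin is recorded for the untreated cells. What is called the IFNG effect below may therefore include albumin, which the recorded design cannot separate. Per the labels' design text, the cells sequenced after sorting were those with low PD-L1.

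The 4 screen files hold read counts per single guide RNA (sgRNA), deposited by the authors as raw whole numbers; per the submitters' processing notes, cutadapt 1.12 was used and the genome build was hg38. How reads were matched to sgRNAs is not given in the sources used here. A further deposited table pairs each of the 10722 sgRNAs with its spacer and target gene. It lists 1572 target symbols, 1453 of them with 7 sgRNAs, and 1571 Ensembl gene IDs, of which 1567 were found in the gene name table used here; EGFP carries no ID. The table lists no sgRNA as a non-targeting control. Libraries were joined by sgRNA name, because the order of rows differs between the files.

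The 12 RNA files are per-transcript output of Salmon 0.13.1, per the submitters' processing notes, on build hg38. The authors deposited estimated counts and TPM for 203027 Ensembl transcripts in each library, with transcript lengths. Estimated counts need not be whole, since Salmon divides reads between transcripts that share sequence, and they were rounded before testing. The tests had been fixed for counts summed per gene. The files give transcript IDs only, and neither they nor the gene tables used here pair those IDs with genes, so the tests were run per transcript with the same model. For that reason the RNA level of MLLT6 and CD274, the check of the knockout on its own target and the tests of the fixed gene lists in the RNA data were not analysed here, and at most 4 transcripts are named, by ID.

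RNA differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, robust fit, TMM scaling, two-sided) on all 12 libraries with 1 mean per group, so that the 4 groups share an estimate of the spread; the robust option was chosen after the data were seen. The filterByExpr filter left 79882 of the 149680 transcripts with a read, and these held 99.21% or more of the estimated reads in each library. Adjusted p-values are Benjamini-Hochberg values over all transcripts tested, with a threshold of 0.05. The comparisons were knockout against wild type without and with IFNG, the IFNG effect in each genotype, and the interaction, which is the IFNG effect in knockout minus that in wild type. The rule for named transcripts, fixed before the data were examined, required an adjusted p under 0.05, a mean count of at least 20 in a compared group and values that did not overlap between the groups, and ordered by fold change. After the data were seen, it was applied to the IFNG effect in wild type for the 2 that rose and to the knockout without IFNG for the 2 that fell. On simulated counts for the IFNG effect in wild type, over the same 79882 transcripts with 200 changed, the test recovered 25% of 100 changes of 2-fold and 67% of 100 changes of 4-fold, with 1 false call. The changed transcripts were drawn among those with a mean count of at least 50, so recovery at lower counts was not measured. Replicate libraries differed by 12.6 to 14.3 times the counting variance, which does not show whether they are separate cultures, and each was used as 1 sample. Alternatives were other scalings, low-count filters, a fold minimum, length offsets, the replicate number as a block, fits on the 6 libraries compared, leaving out each library, DESeq2 1.42.0, and limma 3.58.1 on log2 TPM.

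The screen has 1 library per group, so no test across replicates exists and no p-value is given. The share of reads of an sgRNA carries an exact Clopper-Pearson 95% interval, and the ratio of 2 shares an exact conditional 95% interval. A count of 0 allows up to 3 reads, and a fold against 0 is given as a bound against 3 reads. Reads were amplified by PCR without molecular identifiers, so intervals and floors cover counting error only. An sgRNA was measured in a comparison if it had at least 20 reads in either library, and was called higher or lower at a 4-fold ratio of its shares of the library totals, with 1 read added to each count. Genes were named, by a rule fixed before the data were examined, if at least 2 of their sgRNAs passed 4-fold, ordered by that number and then by the median ratio (the first 10), together with CD274, MLLT6 and the library's members of 2 fixed lists: interferon gamma signalling, and DOT1L and MLL complexes. CMTM6, also in the rule, has no sgRNA in the library. Results for some genes, and for lists that hold them, are not reported here. Other sgRNAs named below were chosen after their values were seen, and are marked so. A gene's or list's median was placed among 10000 random sgRNA sets of the same size matched on abundance. The matching used the mean share in both compared libraries for the first comparison; for the sorted libraries it used the mean of both unsorted libraries, a departure from the plan made because the sorted reads are themselves the outcome. A second matching, on the infected library alone, was added after the data were seen. In a simulation of the sorted library without IFNG with 10 genes changed 8-fold, all 10 were recovered by the 2-sgRNA rule with no other gene. The changed genes were chosen to have well-covered sgRNAs, and reads were drawn from the shares before sorting. The real sorted library had 7388 of 10722 sgRNAs at 0 reads, a loss the simulation left out. The simulation therefore does not measure missed or false genes under such loss.

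Gene coordinates come from the RefSeq gene table of assembly GRCh38.p14, the same build as hg38, counted from 1; 1551 of the 1572 target symbols had a position. The cut site of an sgRNA was not determined, since no genome sequence was used here. Analyses outside R were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.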

Results

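A pair of experiments addressed how PD-L1, an immune checkpoint ligand encoded by CD274, is regulated. In the first, RKO cells with an EGFP reporter of PD-L1 were infected with a library of 10722 sgRNAs, and sgRNAs were counted in 4 libraries: the infected cells (8572675 reads), the cells before sorting (11015949 reads), and cells sorted on the reporter without IFNG (6987402 reads) or with IFNG (6771809 reads). Each of these is a single library. In the second, RNA was sequenced from U2OS cells labelled mock (called wild type here) or MLLT6 knockout, each without or with IFNG, 3 libraries per group. Estimated reads ranged from 16090680 in replicate 3 of the untreated wild type to 19566653 in replicate 2 of the untreated knockout. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Levels of MLLT6 and CD274 RNA were not analysed here, because the transcripts are given by ID only.

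The comparison of the library before sorting with the infected library shows which sgRNAs became rarer or more common before the sort. All 7 sgRNAs fell by 4-fold or more for RPL11 (a ribosomal protein), PSMD7 and PSMC2 (proteasome subunits), COPA and COPB1 (coatomer subunits of vesicle transport), CDK1 and CDK7 (cyclin-dependent kinases), BUB1 (a spindle checkpoint kinase) and CREBBP (a histone acetyltransferase), which are among the first 10 genes by the rule. With counts of 0 set to 3 reads, the median sgRNA was 343-fold lower for RPL11, 323-fold lower for COPB1 and 315-fold lower for CDK7. The 5 cell cycle genes in the library (35 sgRNAs measured) had 29 sgRNAs lower and none higher.

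Lower sgRNAs were not limited to these genes. Of 10591 sgRNAs measured, 5045 (47.6%) were lower and 454 (4.29%) higher. The share of sgRNAs with no read rose from 0.177% to 33.5%. Among 1511 genes with at least 5 measured sgRNAs, 48 had all of them lower, against 10.0 expected if the same share of sgRNAs were lower without regard to the target. CD274 kept 5 of its 12 sgRNAs at less than 4-fold loss and MLLT6 5 of 7. In the DOT1L and MLL complex list (8 genes), 24 of 52 sgRNAs were lower, and the median ratio lay at percentile 44.4 of 10000 matched sets.

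Gains were smaller and involved a minority of each gene's sgRNAs. PEAR1, CCDC90B, NCR3LG1, IL10RB, EHF, MPZL1 and CDYL each had 3 sgRNAs higher by 4-fold or more, and HTR3D, GRK6 and MECOM had 2. PEAR1 and MECOM also had 3 sgRNAs lower by 4-fold or more. CCDC90B, NCR3LG1, IL10RB and MPZL1 had 2 lower each, and EHF, HTR3D and GRK6 had 1 each. The median log2 ratio over all sgRNAs was 1.43 for PEAR1 and 1.54 for GRK6, while that of CDYL was -5.46 with counts of 0 set to 3 reads, as its other 4 sgRNAs fell. In all, 55 genes had 2 or more sgRNAs higher, a number that fell to 15 when ratios were centred on the median sgRNA. All 7 measured EGFP sgRNAs stayed within 4-fold, with a median log2 ratio of 1.21 (chosen after the values were seen).

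Sorting on low reporter signal without IFNG enriched sgRNAs against the reporter itself and some of those against PD-L1. EGFP sgRNAs went from 0.137% of reads before sorting to 65.5% after it, and all 7 measured rose, by 80.1-fold to 1060-fold. CD274 sgRNAs went from 0.117% to 0.956%. CD274-3 (spacer GACCTATATGTGGTAGAGTA) rose 54.0-fold (95% interval 50.9 to 57.4), and CD274-8 (spacer TCCAGATGACTTCGGCCTTG) 5.36-fold (5.23 to 5.49). CD274-12 rose 925-fold (165 to 36600) from a single read before sorting to 587 reads, while its share of 0.0084% after sorting compares with 0.00433% in the infected library. With the infected library as reference, 2 CD274 sgRNAs were higher. EGFP and CD274 were the only genes with 2 or more sgRNAs higher, and the CD274 median lay at percentile 100 of the matched sets, although the median log2 ratio was -2.43 with counts of 0 set to 3 reads. The other 3 of 6 measured CD274 sgRNAs were lower: CD274-1, CD274-2 and CD274-9 fell to 0, 2 and 5 reads. CD274-12 was measured only through its reads after sorting, so the percentile rests in part on that rise. Of the 5 CD274 sgRNAs with 20 or more reads before sorting, 2 were 4-fold higher in either sorted library. CD274 spans bases 5450542 to 5470554 of chromosome 9 (GRCh38.p14, ENSG00000120217).

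MLLT6, on chromosome 17 from 38705273 to 38729795 (ENSG00000275023), had 1 enriched sgRNA. MLLT6-5 (spacer CTGCGTATGTTCGGACGAGA) rose from 603 reads to 9066 reads, from 0.00547% (95% interval 0.00505 to 0.00593) to 0.13% (0.127 to 0.132), or 23.7-fold (21.8 to 25.8). The other 6 MLLT6 sgRNAs, 4 of them with at least 20 reads before sorting, had at most 2 reads after it. The median ratio of the 5 measured MLLT6 sgRNAs lay at percentile 72.9. No sgRNA against IFNGR1, JAK1, JAK2, STAT2 or STAT3 exceeded 5 reads, of 23 with at least 20 reads before sorting, and the highest counts for DOT1L, MLLT10, MLLT3, KMT2A and PSIP1 were 0, 1, 1, 7 and 3 reads. Of all 5785 sgRNAs measured in this comparison, 98.2% were lower by 4-fold or more, so these low counts do not set the genes apart. Besides EGFP and CD274, 61 genes had exactly 1 sgRNA higher by 4-fold or more, and these sgRNAs held 32.5% of the reads. The largest of them, chosen after the values were seen, were TTC31-5 with 297557 reads and AKAP1-2 with 225854 reads. Only 158 sgRNAs had 20 or more reads, and with the infected library as reference 42 sgRNAs were higher instead of 71.

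**Figure D1:**
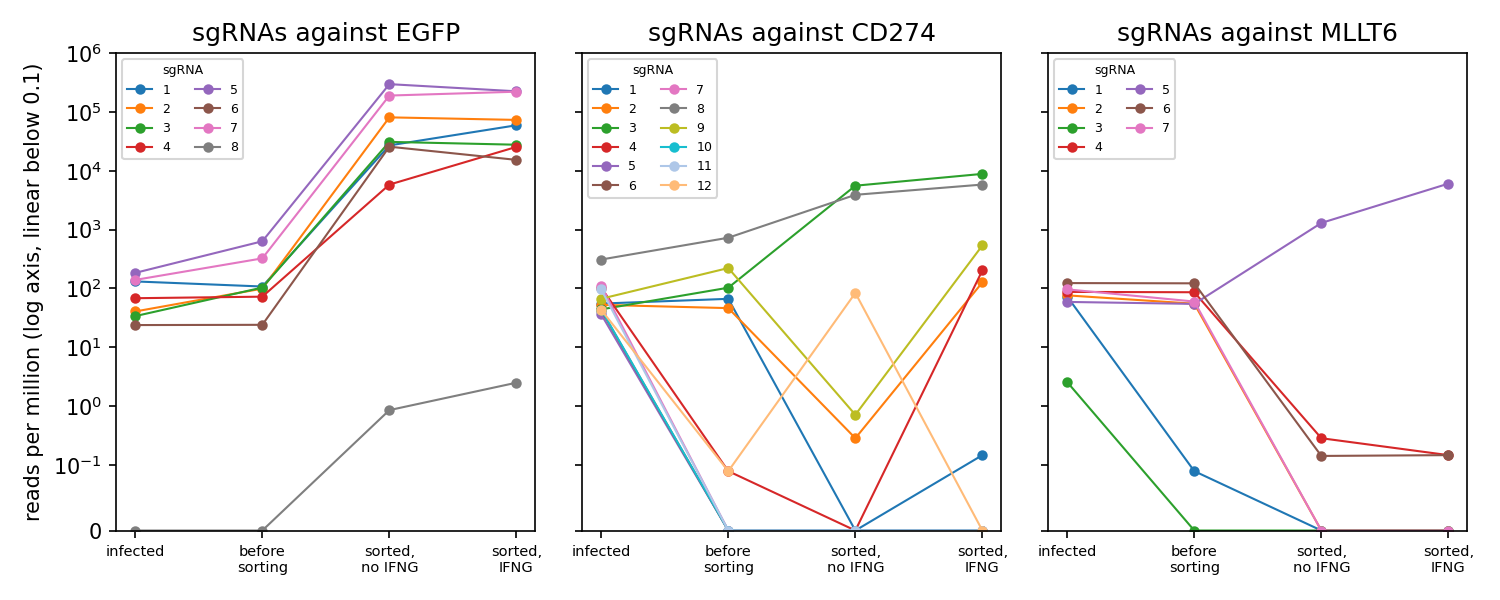
Reads scaled to library size (RPM, vertical axis, logarithmic above 0.1 and linear below) of each sgRNA against EGFP, CD274 and MLLT6 in the 4 screen libraries (horizontal axis), where a line only joins the points of 1 sgRNA. The 7 measured EGFP sgRNAs rose in both sorted libraries, while MLLT6-5 was the only MLLT6 sgRNA to do so.

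With IFNG, a cytokine that induces PD-L1, EGFP and CD274 were again the only genes with 2 or more sgRNAs higher after sorting. EGFP sgRNAs took 64.4% of reads and all 7 rose, by 267-fold to 735-fold over the library before sorting. CD274 sgRNAs took 1.55%, with CD274-3 at 85.8-fold (95% interval 80.9 to 91.0), CD274-8 at 8.0-fold (7.81 to 8.19), and CD274-4 at 2240-fold (401 to 88500) from 1 read to 1376 reads. The share of CD274-4 was 0.0203% after sorting and 0.0103% in the infected library. The CD274 median log2 ratio was 2.23, at percentile 100 of the matched sets, with 3 of 6 measured sgRNAs higher and 1 lower. CD274-4 was measured only through its reads after sorting, so the percentile rests in part on that rise. MLLT6-5 reached 40908 reads, 0.604% of the library (0.598 to 0.61), a 110-fold rise (102 to 120), and the other 6 MLLT6 sgRNAs had at most 1 read. The log2 ratio of MLLT6-5 over the library before sorting was 4.56 without IFNG and 6.78 with it by library totals, and 6.01 and 4.42 when centred on the median sgRNA, a scaling that shifts all sgRNAs of a comparison alike. Between the sorted libraries it was 2.22 higher with IFNG by totals and 2.21 when centred.

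No sgRNA against IFNGR1, JAK1, JAK2, STAT2 or STAT3 exceeded 5 reads. The DOT1L and MLL complex list had 1 of 29 sgRNAs higher (MLLT6-5) and a median at percentile 83.9. Of all 5771 sgRNAs measured, 98.5% were lower and 1.07% higher, so these counts do not set the genes apart. Single sgRNAs of 52 genes other than EGFP and CD274, MLLT6 included, were higher and held 32.9% of reads, and 98 sgRNAs had 20 or more reads.

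The libraries sorted with and without IFNG were then compared with each other, to see which sgRNAs differed with the treatment. CD274 was the only gene with 2 or more sgRNAs higher with IFNG. CD274-2 had 861 reads with IFNG and 2 without (444-fold, 95% interval 123 to 3670), CD274-9 had 3651 and 5 (753-fold, 323 to 2320), and CD274-4 had 1376 and 0 (at least 473-fold higher against a floor of 3 reads). CD274-12 went the other way, with 587 reads without IFNG and 0 with it. MLLT6-5 was 4.66-fold higher (4.55 to 4.76).

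EGFP sgRNAs differed little as a group, with a median log2 ratio of -0.14 and a range of 0.597-fold to 4.37-fold, the last being EGFP-4. Among sgRNAs chosen after the values were seen, BMPR2-7 had 46065 reads with IFNG and 22 without (2160-fold, 1430 to 3450). Of 186 sgRNAs measured, 40 were higher and 91 lower with IFNG. Of the 158 sgRNAs with 20 or more reads without IFNG and the 98 with it, 70 were shared, against 1.44 expected of independent sets.

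**Figure D2:**
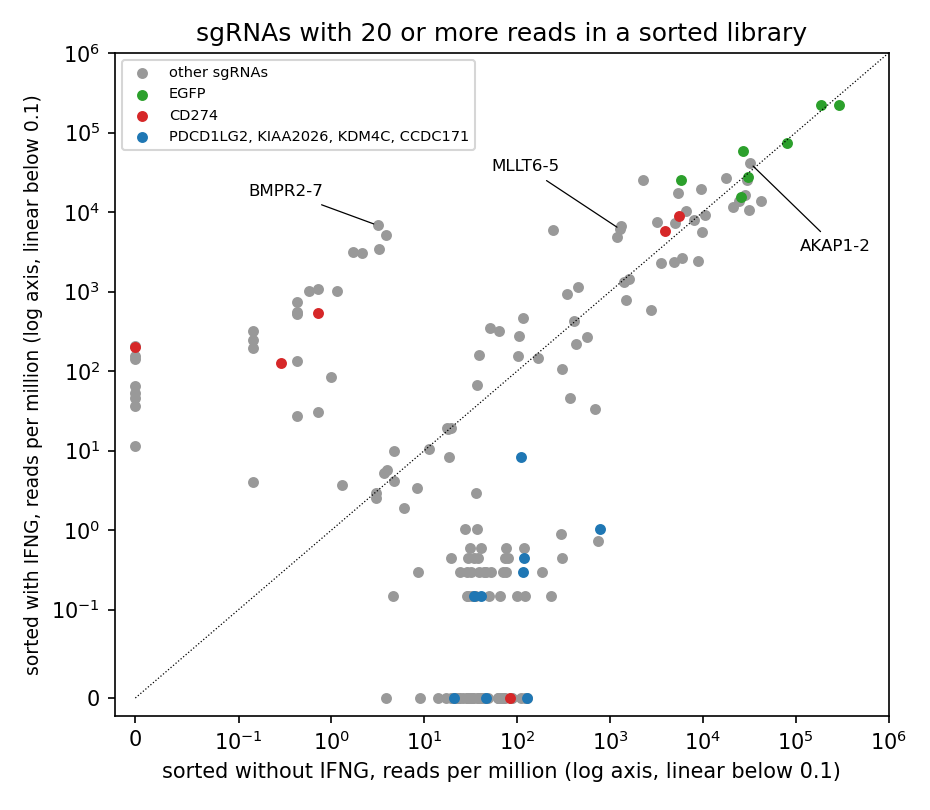
Reads scaled to library size (RPM) of each sgRNA with 20 or more reads in a sorted library, without IFNG (horizontal axis) against with IFNG (vertical axis), both axes logarithmic above 0.1 and linear below. Most EGFP sgRNAs lie near the dotted line of equal values, MLLT6-5 lies 4.66-fold to the IFNG side, and BMPR2-7 had 22 reads without IFNG.

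The RNA libraries compare MLLT6-knockout with wild-type U2OS cells, to see what changes when MLLT6, a chromatin protein linked to the DOT1L methyltransferase, is lost. Without IFNG, 14349 transcripts were higher and 15722 lower in the knockout, 37.6% of the 79882 tested (edgeR, adjusted p under 0.05). ENST00000472056.5 had 12283, 11693 and 10901 reads in the wild-type libraries and 0 in all 3 knockout libraries (edgeR adjusted p = 6e-10). With 3 reads set for the knockout group it was 12800-fold lower, and it was lower in 3 of 3 libraries. ENST00000371817.7 fell from 567 ± 16.2 CPM (counts scaled to library size, SD, n = 3) to 0 reads, 10700-fold with 3 reads set for the knockout group (edgeR adjusted p = 4.6e-09). Folds against 3 reads cover counting error only, since an estimate of 0 can also come from reads divided between similar transcripts. ENST00000472056.5 and ENST00000371817.7 were the 2 transcripts with the lowest fold change that met the rule.

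With IFNG, 14002 transcripts were higher and 16567 lower in the knockout. With a transcript length trend removed, a setting chosen after the data were seen, the balance turned to 16682 higher and 14204 lower with IFNG and to 15511 and 14582 without it. The lists of both treatments overlapped, as 11396 transcripts were higher and 13096 lower in both, against 2520 and 3260 expected of independent lists, and the lists share no library. ENST00000472056.5 again had 0 reads in all 3 knockout libraries with IFNG, and ENST00000371817.7 had 1 read in total. The first principal component held 50.7% of the variance and separated the 6 knockout from the 6 wild-type libraries. Transcripts of 1 gene share sequence, so the reads of a single transcript are uncertain, and the labels do not say how many knockout clones the 6 knockout libraries came from.

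**Figure D3:**
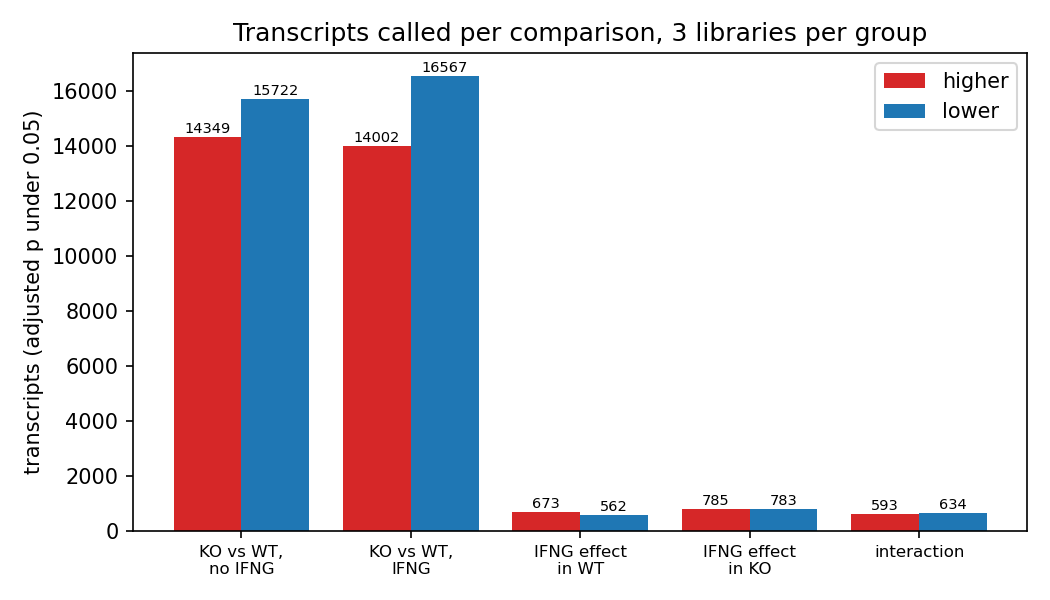
Number of transcripts (vertical axis) with an adjusted p under 0.05 in edgeR, higher in red and lower in blue, for each of 5 comparisons (horizontal axis; KO is MLLT6 knockout, WT is wild type), with 3 libraries per group. The knockout comparisons called 14002 to 16567 transcripts in each direction, the IFNG and interaction comparisons 562 to 785.

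Fewer transcripts passed the test for IFNG than for the knockout. In wild-type cells, 673 transcripts rose and 562 fell, with RLE scaling 625 rose and 786 fell, and with a transcript length trend removed, a setting chosen after the data were seen, 527 rose and 1381 fell. ENST00000395388.6 went from 0 reads in 3 of 3 untreated libraries to 282 ± 7.48 CPM (SD, n = 3), 4840-fold with 3 reads set for the untreated group (edgeR adjusted p = 0.0011). ENST00000377795.7 went from 0 reads to 144 ± 2.72 CPM, 2480-fold in the same way (edgeR adjusted p = 0.0011). Both folds cover counting error only, not the division of reads between similar transcripts. Of the transcripts that rose, 359 rose by 2-fold or more, and of those that fell, 62 did. The number that fell was 352 without replicate 3 of the untreated wild type, and the number that rose was 434 or 431 without replicate 1 or replicate 3 of the treated wild type.

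In knockout cells, 785 transcripts rose and 783 fell with IFNG, 218 and 109 of them by 2-fold or more. ENST00000395388.6 had 0.782 ± 0.677 CPM without and 2.41 ± 0.911 with IFNG, a difference that did not pass the threshold (edgeR adjusted p = 0.49). ENST00000377795.7 had 0.0357 ± 0.0619 and 0.444 ± 0.408 (edgeR adjusted p = 0.39). Without IFNG, ENST00000395388.6 was higher in knockout (edgeR adjusted p = 0.031), with 22, 0 and 22 reads against 0 in the wild type, or in 2 of 3 libraries. With IFNG, both were lower in knockout than in wild-type cells (edgeR adjusted p = 0.00015 and 7.2e-05), and every knockout library lay below every wild-type library. Between the genotypes, 193 transcripts rose in both and 86 fell in both, against 6.61 and 5.51 expected of independent lists, while 96 of the 375 called in both genotypes moved in opposite directions. Across all transcripts, which are not independent replicates, the IFNG effects in the genotypes had a Pearson correlation of 0.02.

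The interaction tests whether the IFNG effect differed between the genotypes. It was more positive in knockout for 593 transcripts and more negative for 634 (edgeR, adjusted p under 0.05), and with a transcript length trend removed for 1240 and 448. ENST00000395388.6 was among the latter (edgeR adjusted p = 0.0078), while for ENST00000377795.7 the difference did not pass (edgeR adjusted p = 0.33). Among 813 transcripts higher with IFNG on average over both genotypes, 156 had a smaller and 130 a larger response in knockout by this test. Among the 351 of them at 2-fold or more, 99 had a smaller and 40 a larger response, and 85 of these 139 transcripts had no read in at least 1 group. With counts of 0 set to 3 reads, the median log2 fold change of the 351 was 2.74 in wild type and 1.76 in knockout. Among 901 transcripts lower with IFNG on average, 194 had a stronger and 90 a weaker reduction in knockout, with a median log2 fold change of -0.19 in wild type and -0.26 in knockout. All these counts use the sign of the interaction, so transcripts that moved in opposite directions in the genotypes are included. DESeq2 called 2366 and 2074 transcripts in the interaction, and limma on log2(TPM + 1) called 189 and 340.

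**Figure D4:**
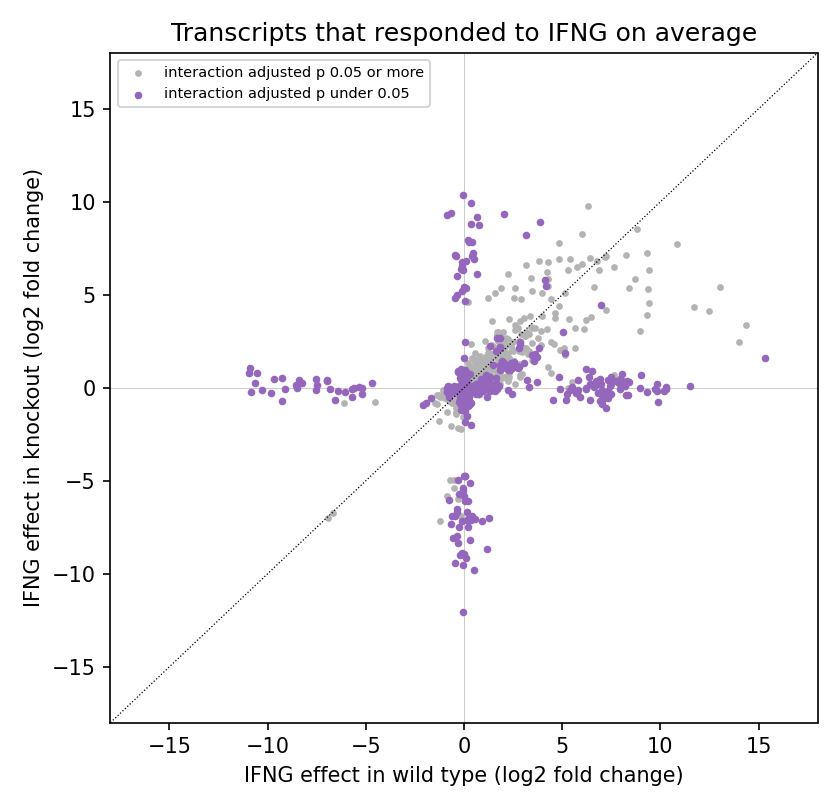
Fitted log2 fold change with IFNG in wild-type cells (horizontal axis) and in knockout cells (vertical axis) for the transcripts that responded on average over both genotypes, with the interaction past the threshold in purple. Each axis compares 3 libraries with 3, and the dotted line marks equal effects; transcripts with no read in a group, among them 85 of the 286 induced and 73 of the 284 reduced transcripts past the threshold, have fitted values that depend on the prior count.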

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

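The test of direction among IFNG-induced transcripts was chosen after the interaction had been seen. The response to IFNG differed between wild-type and knockout U2OS cells by the interaction test itself: the effect was higher in knockout for 593 transcripts and lower for 634 (edgeR, adjusted p under 0.05). ENST00000395388.6 was singled out with them (edgeR adjusted p = 0.0078), with 5156, 5396 and 5111 reads in the wild-type libraries with IFNG, none without it, and 126 reads in total in the 3 knockout libraries with IFNG. Of the 1227 transcripts past the threshold, 177 had no read in at least 1 group.

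A hypothesis is that induction by IFNG is weaker in knockout cells. Of the induced transcripts past the interaction threshold, 54.5% had a smaller response in knockout, between the 50% or fewer that would argue against the hypothesis and the 60% that it needs, so it stays open. A smaller response here includes one in the opposite direction. Among those induced 2-fold or more the share was 71.2%, and 85 of these 139 transcripts had no read in at least 1 group. Of the 284 reduced transcripts past the threshold, 31.7% had a smaller response in knockout, and among those reduced 2-fold or more it was 44.7%, with no read in at least 1 group for 73 of 76. Whether this balance holds under other scalings was not tested. By the count of other splits, chance was not excluded for the interaction: of 30 drawn splits of the libraries within genotypes, 2 called at least 1227 transcripts, the real one included, and the other called 1714. That other split exchanges the treatments of 1 genotype entirely and so measures the average IFNG effect, a structure of the samples, while the 28 splits that mix treated and untreated libraries called 36 to 275. Mixing puts a real IFNG effect into the within-group spread, so these low counts do not measure what chance alone would call.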

How the results depend on the processing

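The alternatives with libraries thinned to equal totals and with a transcript length trend removed were chosen after the data were seen. No named transcript or sgRNA changed sign under any alternative run, but the balance of higher against lower counts turned under some. With libraries left out set apart, 133 values of the main counts stayed within 1.5 times under the alternatives and 39 did not. The cause was not tested for the others, except that a fold minimum, a filter and a smaller set of libraries remove transcripts or samples by construction.

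In the screen, centring on the median sgRNA gave 196 sgRNAs and 15 genes higher before sorting than in the infected cells, and a fold threshold of 2 gave 1917 and 550. With the infected library as reference, 42 sgRNAs were higher after sorting without IFNG. A fold threshold of 2 gave 2 genes higher with IFNG than without.

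In the RNA data, a mean count of at least 50 left 10899 transcripts lower in knockout with IFNG. With a fold change of at least 2, 9354 and 9139 transcripts were higher in knockout without and with IFNG, 359 rose and 62 fell with IFNG in wild type, 218 and 109 in knockout, and 100 and 253 were higher and lower in the interaction. Fits on only the 6 libraries compared gave 350 lower with IFNG in wild type, and 504 higher and 480 lower in knockout. With limma on log2(TPM + 1), 345 rose and 426 fell with IFNG in knockout, and 189 and 340 were higher and lower in the interaction. With limma on log2(TPM + 0.1), 9426 were higher in knockout without IFNG, 345 rose and 475 fell with IFNG in knockout, and the interaction held 198 and 305. With the length trend removed, 1381 fell with IFNG in wild type and 1240 were higher in the interaction. That correction also turned the balance for the knockout, to 15511 higher and 14582 lower without IFNG and 16682 and 14204 with it, and length offsets gave 15130 and 14936 without IFNG. The interaction turned to 740 higher and 588 lower with RLE, 624 and 550 after thinning and 525 and 478 without a filter, and IFNG in wild type to 625 and 786 with RLE and 612 and 655 after thinning. For IFNG in knockout, near balance at 785 and 783, lower counts exceeded higher ones under DESeq2, limma, thinning and a mean count of at least 50. DESeq2 called 2039 and 2673 with IFNG in wild type, 2327 and 2373 in knockout, and 2366 and 2074 in the interaction.

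Leaving out 1 library at a time gave 431 to 617 transcripts higher with IFNG in wild type and 352 to 653 lower. The lowest values came without replicate 3 of treated wild type (431) and replicate 3 of untreated wild type (352), and 434 were higher without replicate 1 of treated wild type. The other counts stayed within 1.5 times. Without any 1 of the treated wild-type libraries, the balance turned for IFNG in wild type and for the interaction.

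With the replicate number as a block, 399 rose and 337 fell with IFNG in wild type, and 352 and 413 were higher and lower in the interaction. Deviations of same-numbered libraries correlated at -0.013 to 0.019, and in 4 of 18 cases the best match was the library of the same number. This gives no sign that the numbers pair the samples, but it cannot exclude a shared day or culture.

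Comparison with non-targeting sgRNAs, tests of gene lists in the RNA data and fold changes of CD274 and MLLT6 RNA were not run. In the sorted libraries 158 and 98 sgRNAs had 20 or more reads and 10 sgRNAs held 78.9% and 74.7% of the reads, so results there rest on few sgRNAs.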

Other observations

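The tests on sgRNAs shared by both sorted libraries and on chromosome 9 were chosen after the results had been seen, as were the thinning and length corrections of the RNA data. Among the checkpoint ligands (CD274, PDCD1LG2, CD276, TNFRSF14, PVR, CD47 and NT5E), PDCD1LG2-3 against the gene of PD-L2 was the 1 sgRNA outside CD274 higher after sorting, with 0 reads before sorting and 145 after sorting without IFNG, at least 76.2-fold higher. This rests on the count of 0 before sorting, since its share of 0.00208% after sorting lay below the 0.0167% in the infected library. Of the sgRNAs with 20 or more reads after sorting, 20 without IFNG and 5 with it had 0 or 1 read before sorting.

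Other single sgRNAs, chosen after their values were seen, rose only with IFNG. RUNX2-5, against an osteoblast transcription factor, had 8074 reads before sorting, 27 without IFNG and 34696 with it, 6.99-fold above the library before sorting (95% interval 6.82 to 7.16). JARID2-7, against a subunit of the Polycomb repressive complex, had 6736, 12 and 21020 reads, a 5.08-fold rise (4.94 to 5.22). PSKH1-6, against a protein kinase, had 5197, 23 and 23189 reads, a 7.26-fold rise (7.04 to 7.48). Outside EGFP reads, MLLT6-5 made up 0.00548% of the library before sorting, 0.376% after sorting without IFNG and 1.7% with it.

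The sorted libraries shared 70 sgRNAs with 20 or more reads, while 88 had them only without IFNG and 28 only with it. Abundance before sorting does not account for this, since 10000 draws weighted by it shared 17 at most. Carry-over of reads between the libraries is argued against, for the 43 with 5000 reads or more in either library as a set, by the median ratio of the smaller to the larger share, 52%. The lowest ratio among them was 0.0463%, so carry-over stays open for single sgRNAs. Shared sgRNAs with fewer reads were not covered. Loss of the target gene stays open: 0% of 94 other sgRNAs against 33 of the target genes were 4-fold higher, but EGFP and CD274, the genes with 2 or more higher sgRNAs, had been left out, so this count decides nothing. Cells of low reporter signal present before the arms were divided remain a candidate explanation that was not tested.

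Near CD274 on chromosome 9 (GRCh38.p14), 9 of 49 sgRNAs within 20 Mb on the centromeric side, against PDCD1LG2, KIAA2026, KDM4C and CCDC171, had 20 or more reads after sorting without IFNG, or 18.4% (95% interval 8.76 to 32.0), against 0 of 20 on the telomeric side (0 to 16.8%) and 1.28% on other chromosomes. Abundance before sorting is argued against by 10000 matched sets, which reached 7 at most, and carry-over by the reads of these sgRNAs with IFNG, 0.714% of those without. A hypothesis is that cuts there may remove the chromosome end that carries CD274, which goes with the absence on the telomeric side. That absence decides little, given the 1.28% on other chromosomes, and the intervals of both sides overlap. The intervals also treat sgRNAs against the same gene as independent. Not every centromeric gene had such sgRNAs: UHRF2, between KIAA2026 and KDM4C, had at most 4 reads per sgRNA, and PSIP1, near CCDC171, at most 3. This goes against an effect of position alone. After sorting with IFNG, 1 of 49 and 1 of 20 sgRNAs had 20 or more reads, and most of the 9 sgRNAs without IFNG stayed below their share before sorting. Without KDM4C 5 of 42 remained, below the 7 that matched sets of the full 49 reached, so the argument against abundance depends on KDM4C. Windows of 10 and 40 Mb gave 8 of 35 and 9 of 105, so the wider window added sgRNAs but none with 20 or more reads.

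The difference between knockout and wild type without IFNG covered 37.6% of the transcripts tested. Unequal depth does not account for this number, since 29584 transcripts, 98.4% of the number at full depth, were called after thinning. Transcript length does not account for the number either, since 30093 (100%) were called with the length trend removed. That correction did turn the balance of higher against lower, and whether the same transcripts were called was not compared. Reads assigned to one or another similar transcript could contribute: pairs of replicates held a median of 1016.5 transcripts at 0 reads in 1 library and 100 or more in the other, 33% of the 3082 in pairs of different genotype, which leaves this open. MLLT6 loss and other differences between the knockout and wild-type cell populations, which the design cannot separate, stay open and untested.

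In fits on the 6 libraries of each comparison, the real split called 27975 transcripts for knockout without IFNG, 29148 with IFNG, 886 for IFNG in wild type and 984 in knockout. In each, 1 of 10 splits called as many, the real one, and the highest other called 0 (edgeR, with 402 to 1949 transcripts at an unadjusted p under 0.05). The 10 splits are too few for a share under 0.05. Every other split also mixes libraries of both groups, so a real difference enters its within-group spread. Low counts there were to be expected, and they do not show what chance alone would call.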
